A study of Homo sapiens with 2 samples.

How the data were processed

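ChIP-seq was carried out on LNCaP cells with an NKX3.1 antibody and with IgG, with 1 library for each. Sequencing libraries were made with an Illumina kit for a Genome Analyzer 2, per the labels' protocols. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The peak caller, its threshold, the handling of duplicate reads and the genome build are not given in the sources used here. There were 2 files without headers. The first lists peaks with coordinates and a score, and that score was used as deposited by the authors, on a scale that no header states. Its lowest value is 80, which has the look of a threshold, and 29 peaks share a value near the top. The second lists 1 bp summits with a height, a signal that the authors deposited as whole numbers and that was not rescaled here. This second file is listed under the IgG sample, but its 41256 summits carry the same numbers as the 41256 peaks and each lies inside its peak. It was therefore read as the summits of the NKX3.1 peaks, and no value of the IgG library on its own was analysed here. Scores and heights are the authors' own values per peak and were used only to describe, rank and filter peaks within this list. Nothing could be said of read depth, so no limit on enrichment was derived from it.

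The build was found from the coordinates. In hg18, 199 peaks on 19 chromosomes would end past the chromosome, and in hg38 this would hold for 115 peaks on 15 chromosomes. In hg19 it held for 0 peaks, and coordinates are given in hg19, counted from 1. Chromosome lengths came from the R package GenomeInfoDb 1.38.1 and Giemsa bands from the table in circlize 0.4.16, whose bands end at the hg19 length on all 24 chromosomes. The gene table at hand describes GRCh38 and was not used to place genes. The plan, fixed before the data were examined, also held annotation of summits, motif searches with 28 motifs and the occupancy of 17 gene lists. These need hg19 sequence or annotation and were not analysed here. The planned rule for this case names the 10 peaks with the highest score, by coordinate. Ordering tied scores by height, the comparisons by band, staining class and spacing, and the score at equal height were chosen after seeing the data. Bands of 3 of the 10 genes on the planned list are not reported here.

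Peak densities were computed in place of the planned density per Mb of known sequence as peaks per Mb outside bands classed as centromeric, variable or stalk, and full chromosome length was tried as an alternative. Intervals for densities and their ratios are 95% bootstrap intervals from 2000 resamples of 1 Mb windows, or of bands for the staining classes. Those for heights and score differences come from 500 resamples of 1 Mb windows. Bootstrap intervals and the exact Poisson intervals for single bands cover sampling within this list and counting error only, and Poisson intervals are too narrow where peaks cluster. The score at equal summit height is the log2 score of a peak minus the median log2 score of autosomal peaks with the same height, for heights shared by at least 50 autosomal peaks, averaged per chromosome. Spacing was compared with 100 random placements of as many positions per band, or per 1 Mb window, without leaving out unmappable sequence. Alternatives were the 20628 peaks with the higher scores and peaks under 1 kb apart merged. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

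The statistics were tested on simulated data. With scores shuffled among the 41256 peaks at equal height and nothing planted, the mean log2 difference on chromosome X was -0.00187. With a log2 difference of 0.2 planted on X, the mean recovered was 0.198. The second value follows from the first by construction, so only the first is a test. A density ratio of 0.5 planted on X over 2876 windows was recovered as 0.517, and unclustered positions for 41256 peaks gave a spacing ratio of 0.993.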

Results

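Binding of NKX3.1 across the genome was profiled in LNCaP cells by chromatin immunoprecipitation followed by sequencing (ChIP-seq). LNCaP is an androgen-responsive line derived from a human prostate cancer metastasis, and NKX3.1 is a homeodomain transcription factor of the prostate epithelium. The design had 1 library made with an antibody against NKX3.1 and 1 control library made with non-specific IgG. The deposited values were a single list of peaks with a score each and the position and height of the summit of each peak. The question was where in the genome DNA was enriched with the NKX3.1 antibody. With 1 library per antibody, no value below has a replicate error, and no p-value was computed. The intervals given describe sampling within this peak list only. The read depth of the libraries is unknown from these values.

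The list held 41256 peaks on 24 chromosomes, and together they covered 18.4 Mb, or 0.594% of the assembled hg19 chromosomes. Peaks were narrow, with a median width of 425 bp and quartiles of 344 and 518 bp. The summit lay near the middle of the peak, at a median of 49.8% of the width from the lower coordinate (quartiles 42.0% and 57.7%). The median summit height was 16, with quartiles of 11 and 26 and a range from 5 to 186. Most peaks were therefore low, and 7959 of them (19.3%) had a height of 10 or less. The 331 peaks with a height of at least 100 made up 0.802% of the list. The tallest 4125 peaks held 28.9% of the summed summit height.

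Peak scores ran from 80 to 3176.33 with a median of 162.13. The score followed the summit height across peaks (Spearman's rho 0.835, across peaks, which are not independent replicates), and height also followed width (rho 0.595). At the upper end, 29 peaks shared the identical score of 3100, and 5 peaks lay above it. The tied peaks had heights from 92 to 186, so the score did not rank the strongest sites among themselves. A score above 3100 is therefore not read as stronger enrichment than that of the tied peaks.

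**Figure D1:**
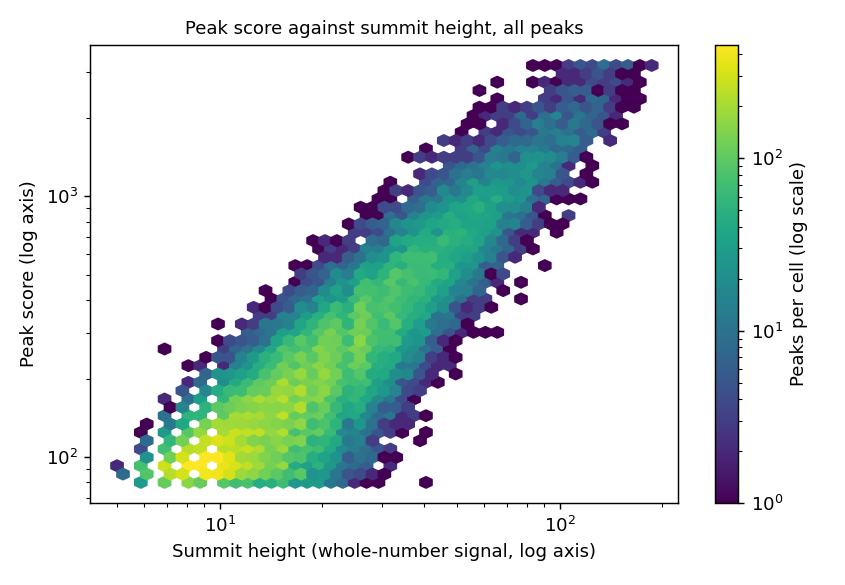
Peak score (vertical, log axis) against summit height (horizontal, whole-number signal, log axis) for all 41256 peaks, with the colour giving the number of peaks per hexagonal cell on a log scale. The cloud is bounded below by the lowest score of 80, and 29 peaks share a score of 3100 at heights from 92 to 186.

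The highest score, 3176.33, belonged to a peak in band 7p15.3 (chromosome 7, 23372487 to 23373064, hg19) with a summit height of 162. The next peak along the chromosome (23374035 to 23374814) had the tied score of 3100 and a height of 185, so this part of 7p15.3 carried a pair of the strongest sites in the list. The other 4 peaks above the tie were found at 19q13.2 (chromosome 19, 41426756 to 41427719, height 80), 7p21.1 (chromosome 7, 20646571 to 20647283, height 117), 10q21.1 (chromosome 10, 59757542 to 59758101, height 137) and 5q13.3 (chromosome 5, 75430389 to 75430988, height 108). The 19q13.2 peak combined a score of 3173.49 with a height below that of every tied peak, and it was wide, at 964 bp. Among the 29 tied peaks the tallest summit of the whole list stood in 7q21.11 (chromosome 7, 81120727 to 81121479), at a height of 186. Among the tied peaks it was followed by the second 7p15.3 peak and by peaks in 3q25.32 (chromosome 3, 158414233 to 158415024, height 166), 4p15.32 (chromosome 4, 16045614 to 16046316, height 164) and 9q31.2 (chromosome 9, 110582011 to 110582649, height 161). These 10 peaks were the highest by score, with ties ordered by height, and not the 10 tallest. By height alone, peaks with lower scores in 17q23.2 (height 175), 8q13.3 (height 172) and 1p36.22 (height 165) came before the 4p15.32 peak. Neither the genes near any of these peaks nor the sequence under them was analysed here, because no hg19 annotation or sequence was used.

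Peaks were spread over all chromosomes at unequal density. Outside centromeric, variable and stalk bands, the autosomes carried 14.9 peaks per Mb (95% bootstrap interval 14.6 to 15.2). Densities ranged from 8.43 per Mb on chromosome 19 to 17.4 per Mb on chromosome 15. On 13 of the 22 autosomes the interval held the autosomal mean. Chromosomes 1, 3, 12 and 15 lay above it, at 16.9, 16.9, 16.8 and 17.4 peaks per Mb, and chromosomes 2, 13, 16, 19 and 22 lay below it. Chromosomes 16, 19 and 22 stood apart from the other autosomes. Chromosome 19, known for its high density of genes, had 427 peaks, 394 of them outside heterochromatic bands, and 0.562 times the density of the other autosomes (0.495 to 0.632). The corresponding ratio was 0.629 for chromosome 16 (0.530 to 0.731) and 0.648 for chromosome 22 (0.522 to 0.781). Among the 20628 peaks with the higher scores, the ratio of chromosome 19 was lower still, at 0.414.

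On the same length basis, the sex chromosomes had the lowest densities of all 24. Chromosome X held 1118 peaks, of which 1116 lay outside heterochromatic bands, at 7.42 per Mb (6.58 to 8.29), which was 0.498 times the autosomal density (0.442 to 0.557). Chromosome Y held 144 peaks, of which 139 lay outside these bands, at 5.15 per Mb (3.30 to 6.96) or 0.346 times the autosomal density (0.222 to 0.470). The value for Y depended on the length used, and it was 0.175 over the full chromosome. Over full lengths, chromosome 22 lay below X, at 6.63 against 7.20 peaks per Mb.

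**Figure D2:**
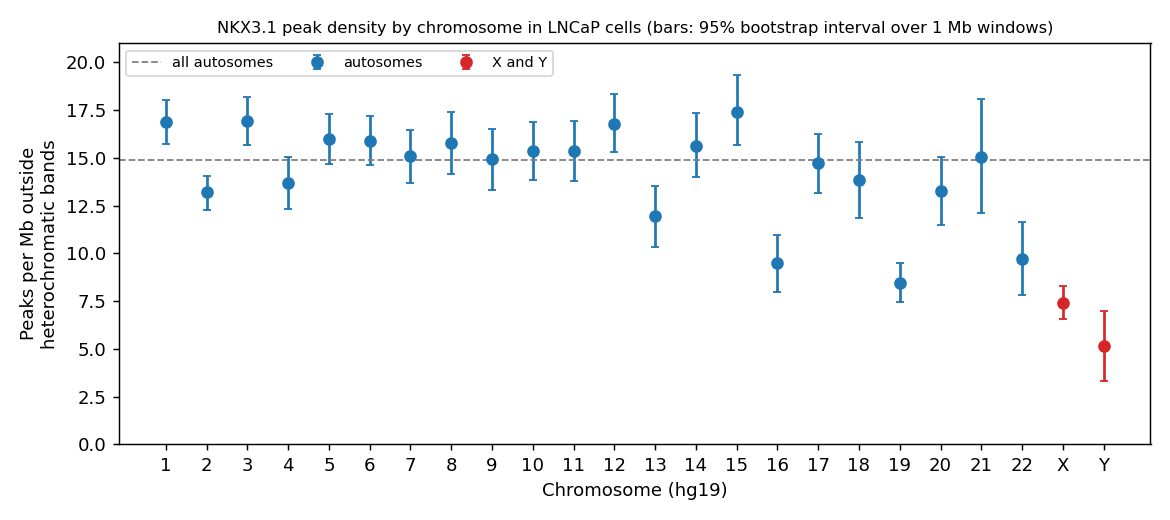
Peaks per Mb outside centromeric, variable and stalk bands (vertical) for each chromosome (horizontal), with bars for the 95% bootstrap interval over 1 Mb windows and a dashed line at the autosomal value of 14.9. Chromosomes 16, 19 and 22 lie at 9.48, 8.43 and 9.70, and X and Y at 7.42 and 5.15.

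Summits on the sex chromosomes were also lower. The median height was 13 on X and 12 on Y, against 15 to 17 on the 22 autosomes. The mean height on X was 16.8 against 22.1 on the autosomes, a ratio of 0.761 (0.726 to 0.795), and the mean on Y was 14.8, a ratio of 0.668 (0.613 to 0.722). The score did not fall in step with the height. At equal summit height, the score on X was 1.17-fold that of autosomal peaks (1.15 to 1.20), a mean log2 difference of 0.23, and the log2 difference on Y was 0.25 (0.19 to 0.30). Among the autosomes, chromosomes 13 and 2 had the highest log2 differences, at 0.14 (0.11 to 0.17) and 0.11 (0.09 to 0.13). On chromosome 2 it was 0.13 on the short arm and 0.10 on the long arm. Chromosomes 19 and 17 had the lowest, at -0.11 (-0.16 to -0.07) and -0.11 (-0.14 to -0.07). Among the 20628 peaks with the higher scores, the difference on chromosome 19 was smaller, at -0.06. That filter removes low scores at a given height, so part of the change may come from the filter itself. Mean summit heights on chromosomes 13 and 2 were 19.8 and 20.05, below those of the other autosomes by ratios of 0.894 (0.856 to 0.930) and 0.899 (0.873 to 0.925). Mean heights were lower by similar ratios on chromosomes 19 (0.890, 0.828 to 0.955), 22 (0.897, 0.826 to 0.958) and 16 (0.907, 0.852 to 0.965), so low summits did not go with high score differences alone.

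**Figure D3:**
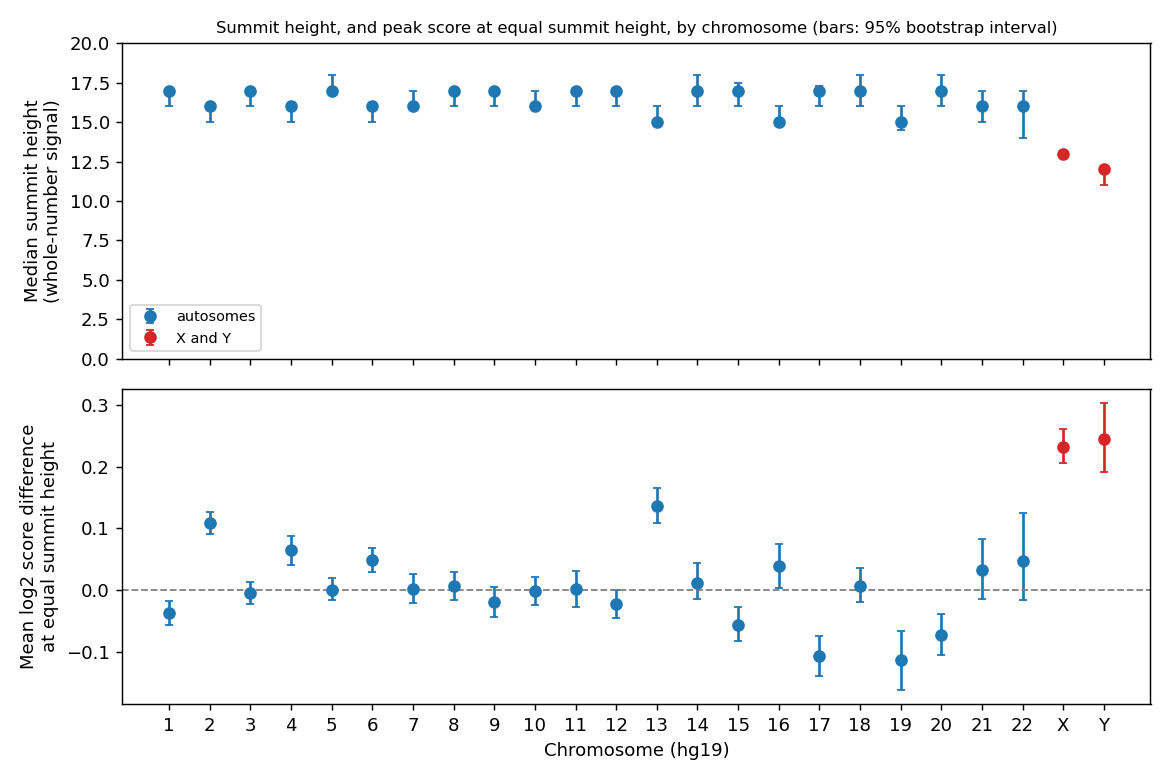
Median summit height (upper panel) and mean log2 difference in score from autosomal peaks of equal summit height (lower panel) for each chromosome (horizontal), with bars for 95% bootstrap intervals. X and Y have the lowest median heights, 13 and 12, and the highest score differences, 0.23 and 0.25, while chromosomes 17 and 19 have the lowest differences, both -0.11 over all peaks.

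Giemsa staining separates chromosome bands into light bands, known to be rich in genes, and dark bands, known to be poor in genes and rich in AT. On the autosomes, the unstained (light) bands carried 15.9 peaks per Mb (15.3 to 16.5), and the darkest class carried 12.5 per Mb (11.5 to 13.6). The 3 intermediate classes lay between these, at 14.3 to 15.1 per Mb. Centromeric bands carried 2.45 per Mb (1.25 to 3.91) and variable heterochromatic bands 1.05 per Mb (0.182 to 2.66). No peak fell in the 23.2 Mb of stalk bands, which allows up to 0.129 per Mb. Unassembled sequence in centromeric, variable and stalk bands cannot hold peaks, so these last values are not comparable with the others. Median summit heights were 16 or 17 in the light, intermediate and dark classes alike. The mean log2 score difference at equal height varied by class, from -0.014 in unstained bands to 0.083 in the darkest class. In the intermediate classes it was -0.027, 0.005 and 0.036, from lighter to darker.

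Single bands differed more than the staining classes, in part by construction, since each class pools many bands. Among 754 bands of at least 1 Mb, the median density was 14.4 peaks per Mb, with quartiles of 10.0 and 18.9. The densest were 1p13.1, with 56 peaks (32.9 per Mb, exact Poisson interval 24.9 to 42.8), and 6q23.3, with 125 peaks (32.9 per Mb, 27.4 to 39.2). Bands 11q23.1 (67 peaks, 31.9 per Mb), 10q21.2 (102 peaks, 30.9 per Mb), 8p21.2 (122 peaks, 29.8 per Mb) and 5q23.2 (174 peaks, 29.5 per Mb) were also among the densest 10. At a scale of 1 Mb, the richest windows held 46 peaks in 4q22.2 to 4q22.3 (chromosome 4, 95000001 to 96000000), 45 in 7q31.31 (chromosome 7, 120000001 to 121000000) and 44 in 3q26.31 (chromosome 3, 171000001 to 172000000). The median heights of these 3 windows, 16, 17 and 17, were like that of the whole list, and their tallest summits had heights of 110, 105 and 92. Over 2640 autosomal windows the variance was 5.21 times the mean, and 164 windows held 30 peaks or more, where 1.05 were computed for an even spread. The longest peak-free stretches outside heterochromatic bands were 4.42 Mb in 16q21 (chromosome 16, 60088188 to 64512361) and 4.01 Mb in 8q24.23 to 8q24.3 (chromosome 8, 136653572 to 140665958).

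Peaks also lay close to one another. Neighbouring summits were under 10 kb apart in 10369 cases, or 25.1% of all distances. Random positions, drawn in the same number within each band, gave a mean of 6240 ± 69.8 (SD, 100 placements) and never more than 6399. The ratio was 1.66. The excess was highest at 1 to 2 kb, where the observed number was 2.47 times the random one. From there it fell to 1.36 times at 5 to 10 kb and 1.11 times at 10 to 20 kb. Under 1 kb the ratio was 2.04, but called peaks never overlapped, while random positions were not kept apart. That lowers the ratio under 1 kb, so the maximum at 1 to 2 kb is not read as a preferred spacing. Drawn within 1 Mb windows, which keeps regional density, random positions still gave a ratio of 1.48 for distances under 10 kb. Autosomal peaks with a neighbour within 10 kb were taller than those without. Their mean summit height was 23.9 (23.6 to 24.25, 17337 peaks) against 20.7 (20.5 to 20.9, 22657 peaks), and their median scores were 173.77 and 154.28.

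**Figure D4:**
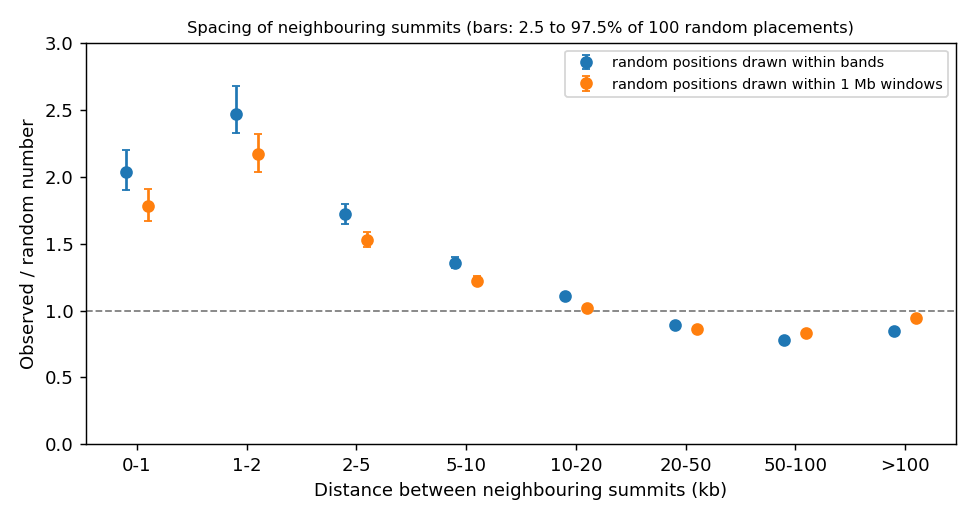
Observed number of distances between neighbouring summits divided by the mean of 100 random placements (vertical), by distance class in kb (horizontal), for random positions drawn within bands (blue) and within 1 Mb windows (orange), with bars for the central 95% of placements. The within-band ratio is 2.47 at 1 to 2 kb and 1.36 at 5 to 10 kb.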

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

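The density ratios of chromosomes X, Y, 3, 16, 19 and 22 stayed on the same side of 1 among the higher-scored peaks, with peaks under 1 kb apart merged and over full chromosome length. The alternatives fixed before the data were examined kept 20628 peaks with the higher scores, or merged peaks under 1 kb apart into 39885 for the summary of the list. Among the higher-scored peaks the ratio of chromosome 19 moved from 0.562 to 0.414, the median score was 294.845, and the median summit height was 25 against 16 in the whole list. Merging for the density ratios and full chromosome length were chosen after seeing the data. Full length moved the ratio of chromosome Y from 0.346 to 0.175 and that of chromosome 22 from 0.648 to 0.473, since it counts heterochromatic bands. The other 15 of 18 density alternatives stayed within the bootstrap interval. A filter on height, chosen after seeing the data and not among these 18, moved the ratios of X, Y, 16, 19 and 22 below their intervals. The same held for chromosomes 2 and 13. Among summits of height 26 or more, the ratios were 0.277 on X (0.215 to 0.339) and 0.126 on Y (0.065 to 0.198). They were 0.486 on chromosome 16, 0.422 on 19 (0.310 to 0.544), 0.491 on 22, 0.721 on 2 and 0.685 on 13. Mean summit heights were lower on all of these chromosomes, which tends to lower a ratio taken among tall summits. The score difference at equal height was 0.21 on X and -0.06 on chromosome 19 among the higher-scored peaks, and 0.23 and -0.12 when width was matched too. Keeping peaks by score cuts the range of the score itself, so smaller differences among the higher-scored peaks are in part built in. The spacing ratio under 10 kb, 1.66 within bands, was 1.48 within 1 Mb windows, 2.01 among the higher-scored peaks and 1.54 with peaks merged. The last fall is fixed by construction, since merging removes the observed distances under 1 kb and not the random ones, and the ratio at 1 to 2 kb rose from 2.47 to 2.58. These score and spacing alternatives were also chosen after seeing the data. Of the 26 alternatives fixed beforehand, 23 need hg19 sequence or annotation and were not run. No replicate could be left out, and no paired analysis was possible because there was 1 library per group. The unknown depth limits how far low peaks can be told from background.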

Other observations

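The bands that carry genes of interest in the prostate, as known from textbooks, were looked up for 7 of the genes on a list fixed before the data were examined, so the values are no tally over that list. The choice to use bands was made afterwards. Each band spans several Mb and many genes, so no peak is assigned to a gene. Bands 17q21.32 (HOXB13, a prostate homeodomain factor, 18.8 per Mb), 8q24.21 (MYC, 17.6 per Mb), 6p21.31 (FKBP5, an androgen-induced gene, 17.4 per Mb) and 21q22.3 (TMPRSS2, an androgen-induced protease, 16.5 per Mb) lay above the median density of 14.4 peaks per Mb over 754 bands. The exact Poisson intervals of these 4 bands all held the median, with lower bounds of 13.8, 13.8, 13.1 and 13.2 in this order. The other 3 lay below it, and the intervals of the last 2 excluded it: 14q21.1 (FOXA1, 11.4 per Mb, 8.80 to 14.5), 2p12 (HK2, hexokinase, 9.40 per Mb, 7.43 to 11.7) and 19q13.33 (KLK3, which encodes PSA, 8.53 per Mb, 5.71 to 12.2). Their surroundings were low too. Chromosome 19 carried 8.43 peaks per Mb outside heterochromatic bands, and the short arm of chromosome 2 carried 11.8. Band 2p12 is also of the darkest staining class, which carried 12.5 per Mb on the autosomes. The low values are therefore not read as particular to these 2 bands.

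The tests below on X, on chromosomes 16, 19 and 22 and on the spacing were written after values of the chromosomes and of the distances between summits had been seen. Fewer copies of a chromosome were weighed only through heights, scores and densities, since copy number was not measured. No other biological explanation was tested, as the design has 1 cell line and 1 condition.

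Summits on X and Y were lower than on the autosomes. On X, a chance run of low summits is argued against, with limits. Of 10000 runs of 1118 neighbouring autosomal peaks, 0 had a mean height at or below the 16.8 of X, and the lowest was 19.1. These runs overlap and reuse the same peaks, so far fewer than 10000 are independent and no small probability can be read from them. X was also tested because its summits had been seen to be low. A score threshold that lets low summits pass where background is low is argued against as the whole cause on X, where the mean height above 26 among summits of height 26 or more was 0.751 times that on the autosomes (0.617 to 0.869). This was not particular to X, as the ratio was 0.757 on chromosome 13 (0.657 to 0.872) and 0.852 on chromosome 2 (0.780 to 0.921). On Y the same ratio, 0.797 (0.316 to 1.26), rests on 13 summits and leaves the threshold open. Fewer copies of X in these cells may lower both the signal and the local background, and this goes with the log2 score difference of 0.23 at equal height (0.21 to 0.26), though the score's definition is not stated and copy number was not measured. The score difference also varied by staining class on the autosomes, up to 0.083 in the darkest class, so it does not reflect copies alone.

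Chromosomes 16, 19 and 22 carried few peaks. Their mix of light to dark band classes is argued against by the class rates themselves. On the autosomes other than these 3, rates ran from 12.7 peaks per Mb in the darkest class to 16.3 in unstained bands. All of these lay above the 9.48, 8.43 and 9.70 per Mb of chromosomes 16, 19 and 22. The ratio of observed peaks to those computed from the class rates, 0.594 (0.531 to 0.671), was largely set by these rates and is no separate support. Fewer copies of chromosome 19 stay open, because its mean summit height was lower (ratio 0.890, 0.828 to 0.955) while its log2 score difference at equal height, -0.11 (-0.16 to -0.07), or -0.06 among the higher-scored peaks, was opposite in sign to that of X. For chromosomes 16 and 22, some values count against fewer copies as the whole cause. They held 0.722 times the density of chromosome 2 (0.626 to 0.834), yet their joint score difference, 0.042 (0.012 to 0.073), lay below the 0.11 of chromosome 2 (0.09 to 0.13). So did that of chromosome 16 alone, 0.04 (0.003 to 0.076). The value of chromosome 22, 0.05 (-0.02 to 0.13), was lower too, but its interval overlapped that of chromosome 2. The arms of chromosome 16 differed: the long arm, at 0.071 (0.017 to 0.128), overlapped chromosome 2, while the short arm had -0.013 (-0.054 to 0.025) at a lower density, 8.15 against 10.5 peaks per Mb. The mean height above 26 among tall summits was 0.969 times that of the other autosomes on chromosome 16 (0.786 to 1.14) and 0.925 times on chromosome 22 (0.710 to 1.14), and these intervals held both 1 and the 0.852 of chromosome 2. The density of such summits was 0.486 times that of the other autosomes on chromosome 16 (0.371 to 0.612). It was 0.491 times on chromosome 22 (0.361 to 0.629) and 0.721 times on chromosome 2 (0.642 to 0.803). Over all peaks these 3 density ratios were 0.629, 0.648 and 0.878. The explanation still stays open, because the score difference did not follow density alone: chromosome 17, at 14.7 peaks per Mb (13.2 to 16.3), had a difference of -0.11, so a value below that of chromosome 2 does not rule out fewer copies. Base composition, mappability and fewer binding sites were not tested here.

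Summits lay closer together than random positions. Uneven density between 1 Mb regions is argued against as the whole cause by the ratio of 1.48 within 1 Mb windows (1.45 to 1.51 over 100 placements). Broad enriched regions cut into several peaks stay open. Distances of 5 to 10 kb were 1.23 times the random number within 1 Mb windows (1.19 to 1.26), so the excess was not confined to shorter distances. A lower bound above 1.1 was at first taken to exclude this explanation, but a region longer than 5 kb would raise the ratio too, and the breadth of such regions was not measured. Clusters of regulatory elements and unmappable sequence within the windows also stay open as possible explanations.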
